A study of Mus musculus with 30 samples.

How the data were processed

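Total RNA of 30 mouse retinas was measured, 1 retina from each pup, 3 pups in each of 10 groups. Per the labels' protocols, RNA was isolated with the RNeasy Mini Kit on a QiaCube, and 100 ng was amplified with the Ovation PicoSL WTA System V2 and biotin-labelled with the Encore module. The deposited table holds 1 log2 value per probe set and array for 22690 probe sets, normalized by the authors before deposit. The submitters' processing notes name Partek, without a version. The summarisation, background correction and normalization methods are not given in the sources used here. The deposited log2 values were used as they are, with no further scaling in the reported results. Groups, injection days and cell doses were taken per the labels. The sample labels give P17 as the stage of every retina, while the protocol text allows collection at P12 or P17 and the series design text pairs P12 with injection at P5. The label was followed for naming only, and no model took the collection day as a term. If the series design text holds, comparisons of P5 groups with other groups also compare collection days.

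Probe sets were joined to genes by the platform's annotation: 64 were controls, 20380 had 1 gene symbol, 691 several and 1606 none, and for 29 with 1 symbol the gene identifier had no match in the RefSeq table. For each symbol the probe set with the highest mean over all arrays was kept among those with 1 symbol, which left 12393 genes. A genome build was not used, so no positions are given. Arrays give no counts, so precision is limited by the number of arrays, 3 per group. Replicates were checked for identity (0 identical pairs) and for pairing by replicate number. Across 14 comparisons the correlations of residuals between arrays of equal number ran from -0.45 to 0.55 and no comparison had all pairs above 0.1, so no pairing was used.

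Differences were tested with limma 3.58.1 in R 4.3.3: 1 mean per group over all 30 arrays (20 residual degrees of freedom), 21 contrasts, moderated statistics by eBayes, two-sided, and Benjamini-Hochberg adjustment over 12393 genes in each contrast. A gene was called changed at an adjusted p under 0.05. Of 38 gene lists written from textbook knowledge of retinal cell types, vessels, hypoxia and stress (718 members, 625 measured), 37 had at least 5 measured members and were tested with limma's camera, two-sided, with the preset correlation of 0.01 and adjustment over lists within each of 10 comparisons. The estimated correlation was the alternative. The lists include cell types that a dissection can bring along, such as lens, pigment epithelium and blood cells. The OIR signature was tested with limma's fry, with 100 genes from each end by moderated t and adjustment over 6 comparisons. Groups, contrasts, lists, tests, most alternatives and the rule for named genes were fixed before the data were examined.

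Genes were named by this rule. For a group against its control: the 8 largest positive and 8 largest negative changes among genes that passed and whose 3 arrays of one group all lay beyond those of the other, or the 3 smallest p where none passed; up to 4 members of each called list with the strongest statistics in the direction of the call; and 12 fixed genes whatever their values (Vegfa, Angpt2, Esm1, Pdgfb, Pdgfrb, Rgs5, Cspg4, Plvap, Pecam1, Gfap, Lcn2 and Cx3cr1). For contrasts between treatments, the 5 largest changes in each direction were taken. The text gives a part of the genes so named. Car12 and Trpm1, the members that moved against their lists, were chosen after their values were seen. Names of mouse genes follow the RefSeq table.

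The alternatives were quantile normalization, median centring, all probe sets as tested features, leaving out genes with a mean in the lowest 30%, a minimum of 1.5-fold, eBayes with trend and robust settings, array weights, a block for replicate number, fitting only the groups compared, the estimated correlation, 50 or 300 signature genes from each end, and leaving out each array in turn. Chosen after seeing the data were covariates for the lens list mean, the hybridisation control mean (18 probe sets) and Xist, and leaving out the 2 P12 arrays of lowest interquartile range. Array weights were computed gene by gene because the default method did not converge, a change made after that warning was seen. Other splits of the same arrays were counted, all 10 for 3 against 3 arrays and 100 drawn with a fixed seed otherwise.

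The pipeline was tested on simulated data with the same groups and 12393 genes, 200 of them changed between OIR and normoxia: 33, 88 and 98% were called at log2 changes of 0.5, 1 and 2, with 5, 5 and 7 false calls. A simulated signature shift of -0.3 was returned as -0.32, and a shifted list was called with 0 of the others. Simulated noise was independent between genes and equal in spread between groups. The simulation therefore tests neither the preset correlation of the list test nor groups of unequal spread. Figures were drawn with matplotlib 3.10.9 and tables with pandas 2.3.3.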

Results

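RNA from 30 mouse retinas was measured on 30 expression arrays, 1 retina per pup, in 10 groups of 3. The model was oxygen-induced retinopathy (OIR), in which pups breathe 75% oxygen from postnatal day 7 (P7) for 5 days, lose central retinal capillaries, and become hypoxic in room air. An untreated normoxia group and an untreated OIR group stood beside 8 injected OIR groups. At P5 or at P12 the vitreous received saline, 100000 human endothelial colony-forming cells (ECFC), 10000 human CD34+ cells, or both together (110000 cells, the combination). Every sample label gave collection at P17, whereas the protocol text allows P12 or P17 and the series design text reads as collection at P12 for injection at P5. The median of each array lay between 8.16 and 8.49 on the log2 scale, and replicates of a group correlated across probe sets with r from 0.964 to 0.997. With 3 arrays per group, the number of arrays limits the precision. Values below are log2 differences ± SE with limma's Benjamini-Hochberg adjusted p over 12393 genes, unless stated otherwise.

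The first comparison asked what OIR did to the untreated retina at P17. Hypoxia and sprouting genes were far higher: Esm1, an endothelial tip cell gene, rose by 4.41 ± 0.48 (adjusted p = 3.6e-06), from 3.77 ± 0.42 to 8.18 ± 0.53 (SD, n = 3). The level in normoxia was as low as that of Eif2s3y, a Y-linked gene, on female arrays (3.84 to 4.83), so the difference is a lower bound. Apln, the tip cell ligand apelin, rose by 3.25 ± 0.35, Adm, the vasodilator adrenomedullin, by 3.16 ± 0.39, and Angpt2, which loosens mural cell contact, by 1.98 ± 0.31. Vegfa, the main hypoxia-driven vessel growth factor, rose by 1.26 ± 0.18 (2.40-fold, adjusted p = 6.4e-05). Pericyte genes rose too: Cspg4, coding NG2, by 1.35 ± 0.18, Rgs5 by 0.80 ± 0.16, Pdgfrb, the receptor that keeps pericytes on vessels, by 0.70 ± 0.17, and its endothelial ligand Pdgfb by 0.77 ± 0.17. The pan-endothelial adhesion gene Pecam1 rose by 1.46 ± 0.17 and the endothelial cadherin Cdh5 by 1.48 ± 0.19.

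In all, 565 of 12393 genes changed, 445 higher and 120 lower. Among the genes with the largest rises were also Stc2 (2.51 ± 0.24, adjusted p = 9.7e-07), Igfbp3 (2.53 ± 0.40), S100a6 (2.53 ± 0.58) and Gimap4 (2.38 ± 0.23). The largest falls among genes that passed and whose arrays separated fully were smaller. Slco1a4, an organic anion transporter of brain vessels, changed by -1.36 ± 0.28, Spc25 by -1.31 ± 0.34, the neurokinin receptor gene Tacr3 by -1.12 ± 0.28 and the neuropeptide gene Cck by -1.05 ± 0.28. The count fell to 242 without OIR replicate 3, 324 without normoxia replicate 3 and 348 when only these 6 arrays were fitted, and was 852 with array weights. The share of changed genes that were higher, 78.8%, was 64.5% after quantile normalization and 53.8% after median centring.

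Of the 37 fixed gene lists, limma's camera called 18 in OIR, 15 higher and 3 lower. In the list of endothelial tip cell and sprouting genes 15 of 16 measured members rose (15 adjusted over the list alone), by 1.72 on average. In the endothelial list 13 of 22 rose (17 adjusted over the list alone), and in the pericyte and mural cell list 13 of 20 (15 adjusted over the list alone). Basement membrane genes rose in 14 of 28 cases (16 adjusted over the list alone), among them Col4a1 by 1.98 ± 0.24 and Bgn by 2.06 ± 0.27. Vessel stabilisation ligands and receptors rose in 8 of 20 (10 adjusted over the list alone), and cell cycle genes in 12 of 23 (17 adjusted over the list alone), led by Rrm2 at 2.25 ± 0.30 and Top2a at 2.25 ± 0.29. With an estimated correlation in place of the preset value these 6 calls held, at adjusted p = 0.0011 for the tip cell list and 0.021 for the others.

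The other calls of OIR against normoxia did not hold that way. In the list of HIF targets and glycolysis 13 of 29 members rose (18 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation). In the gliosis and retinal stress list 3 of 24 passed (10 adjusted over the list alone), among them S100a6 and the metallothionein Mt2 at 1.70 ± 0.44 (adjusted p = 0.38 with an estimated correlation). Gfap, the intermediate filament of reactive Muller glia, stood 2.06 ± 0.72 higher without passing (adjusted p = 0.1), as did Lcn2 at 2.0 ± 1.13 (0.33). Microglia and macrophage genes passed in 3 of 22 cases (12 adjusted over the list alone), the complement genes C1qc at 1.71 ± 0.43 and C1qb at 1.41 ± 0.38 and the microglial gene Aif1 at 1.22 ± 0.34 (adjusted p = 0.4 with an estimated correlation). In the bipolar cell list Scgn fell by 0.64 and Grik1 by 0.83 (2 of 13; 3 adjusted over the list alone; adjusted p = 0.42 with an estimated correlation, and camera's own adjusted p was 0.0567 without normoxia replicate 1).

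**Figure D1:**
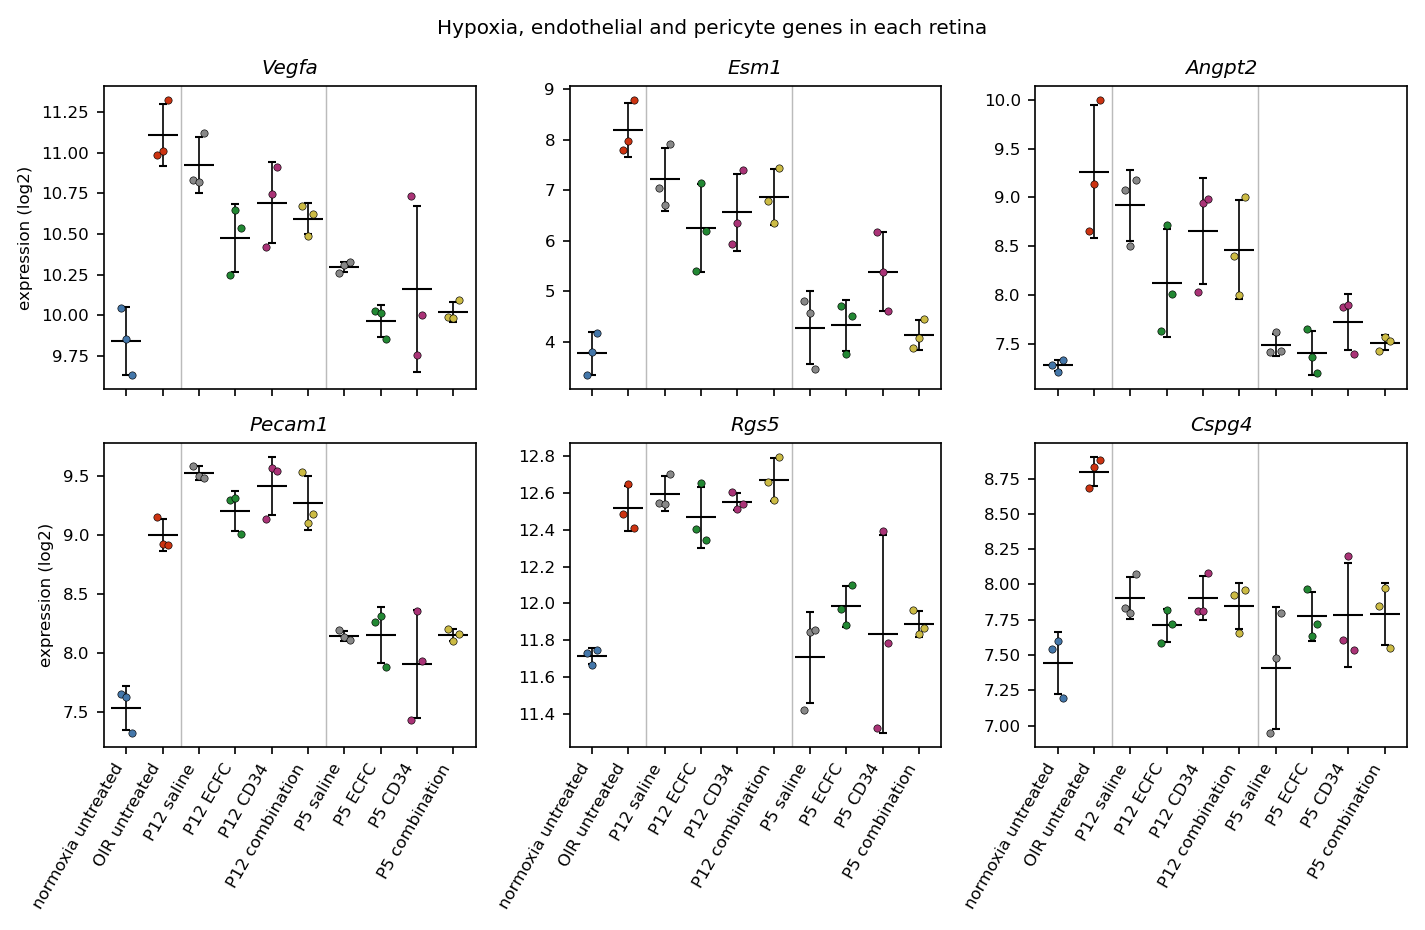
Expression (log2) of 6 hypoxia, endothelial and pericyte genes in each retina. Each point is 1 array, the horizontal mark is the mean of 3 arrays and the bar is ± 1 SD. Esm1 averaged 3.77 in normoxia, 8.18 in untreated OIR and 4.28 in retinas injected with saline at P5.

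Quality measures that moved with injection day are given before the injected groups. The spiked-in hybridisation controls, which hold no retinal RNA, averaged 13.4 ± 0.125 (SD, n = 12) on the arrays of the P12 groups and 12.5 ± 0.306 (SD, n = 18) on all others, with no overlap (lowest P12 array 13.2, highest other array 12.96). Of the others, P5 CD34 replicate 1 (11.86) and P5 saline replicates 2 (11.92) and 3 (12.03) lay lowest, and the next array was at 12.44. For P12 arrays against all others the two-sided permutation p was 1e-05, the smallest the permutations can give. Single arrays were permuted, although injection day varied only between groups of 3, so this p treats arrays of a group as independent. The interquartile range of the P12 arrays was 3.30 ± 0.142 against 3.55 ± 0.101. Lens genes, 14 of them measured, averaged 12.7 ± 1.53 (SD, n = 3) in the retinas given saline at P5, 9.46 ± 0.437 with ECFC, 11.9 ± 3.71 with CD34+ cells and 10.3 ± 1.93 with the combination. In the 6 groups not injected at P5 these means ran from 6.06 (P12 saline) to 7.28 (normoxia). Xist marked 2 of 3 arrays as female in each untreated group, 1, 1, 1 and 0 in the P12 saline, ECFC, CD34 and combination groups, and 1, 1, 2 and 3 in the same P5 groups.

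**Figure D2:**
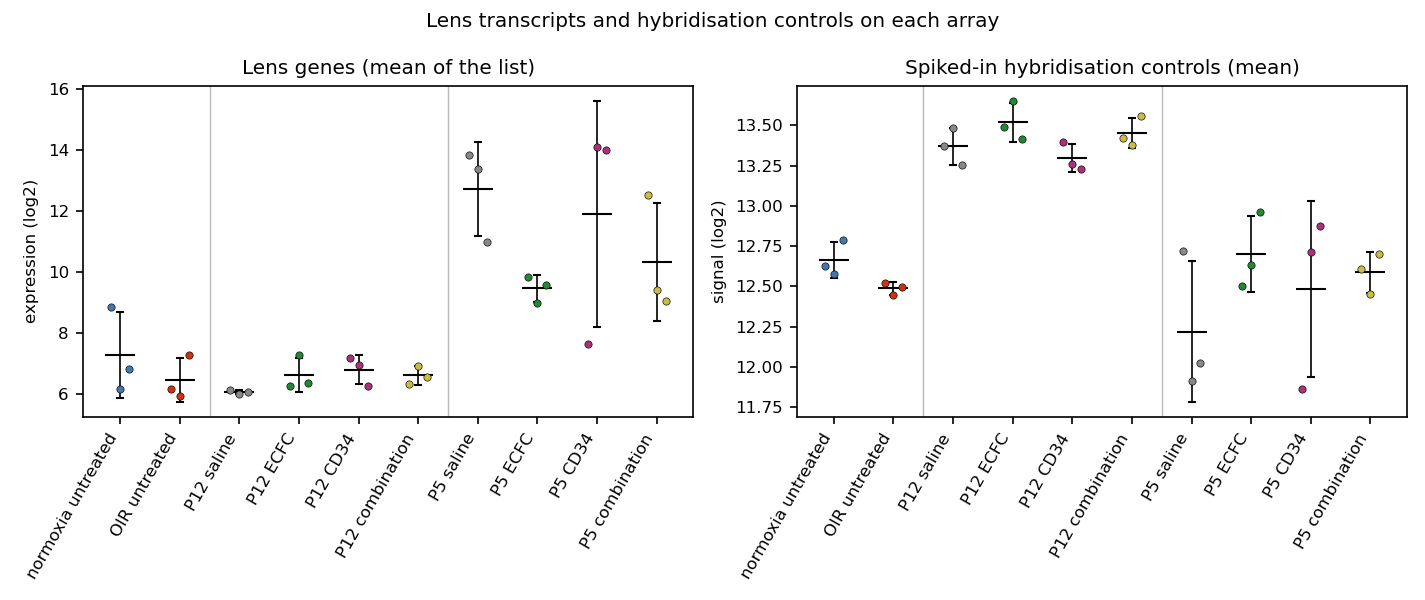
Mean of 14 lens genes (left) and mean of 18 spiked-in hybridisation control probe sets (right), both log2, on each array. Points are arrays, marks are means of 3 and bars are ± 1 SD. The control means of the P12 groups lay at 13.2 or above, those of the other arrays at 12.96 or below, and group means of lens genes were highest in the P5 groups, with CD34 replicate 1 at P5 (7.63) below normoxia replicate 1 (8.86).

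Saline at P12 against untreated OIR asked what injection alone did, on arrays whose hybridisation controls also differed by group (13.4 ± 0.116 against 12.5 ± 0.0399, SD, n = 3). Vessel markers did not move together: Pecam1 rose by 0.53 ± 0.17 (adjusted p = 0.03), while Cspg4 fell by 0.90 (adjusted p = 0.0011) and Plvap, a gene of fenestrated and immature vessels, fell by 0.57 (adjusted p = 0.018). Vegfa (-0.18 ± 0.18), Esm1 (-0.96 ± 0.48), Angpt2 (-0.35 ± 0.31), Rgs5 (0.08 ± 0.16) and Gfap (0.86 ± 0.72) did not pass. Among genes that passed and whose arrays separated fully, Apoe, the main lipid carrier made by glia, fell most (-1.64 ± 0.26, adjusted p = 9.4e-05). Tulp1, a photoreceptor protein gene, fell by 1.29. The largest rises among such genes were those of LOC664787 (2.32 ± 0.63), 2210010C04Rik (1.77 ± 0.37) and Rragd, a GTPase of nutrient sensing (1.57 ± 0.16). In limma's test 2642 genes changed, 738 higher and 1904 lower. The only list called was that of T and NK cells, in which Gzmb (1.09 ± 0.34), Cd2 (0.59 ± 0.19) and Prf1 (0.48 ± 0.09) rose, 3 of 16 members (3 adjusted over the list alone; camera adjusted p = 0.0094, adjusted p = 1 with an estimated correlation, 0.986 after quantile normalization); with dim genes left out it had under 5 members to test. Camera had called that list lower in OIR than in normoxia (0 of 16 members passing, 0 adjusted over the list alone; adjusted p = 0.0385, 0.591 with an estimated correlation). It averaged 5.91, 5.95 and 6.23 in normoxia, 5.86, 5.70 and 5.76 in untreated OIR and 6.14, 6.08 and 6.13 after saline at P12. Gzmb averaged 4.38 in untreated OIR and 5.46 after saline at P12, and Cd2 5.38 in untreated OIR. These lie as low as Eif2s3y on female arrays or Xist on male arrays, so both rises are not estimates of size. The mean interquartile range was 3.44 after saline at P12 and 3.59 in untreated OIR.

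The balance of directions in that comparison depended on scaling: 27.9% of changed genes were higher as deposited, 47.7% after quantile normalization and 68.9% after median centring, which moved the median of all genes to 0.16. The count was 1661 with the hybridisation control mean as a covariate, 1687 without P12 saline replicate 1, 1707 without OIR replicate 2, 5300 with array weights and 3972 when only these 6 arrays were fitted, and with that covariate Pgk2 turned from 1.33 to -0.15 and 4930433N12Rik from 1.25 to -0.16.

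Saline at P5 against untreated OIR asked the same of the early injection, and here hypoxia and vessel genes were lower. If the series design text holds, these groups also differ in collection day (P12 against P17), which this comparison cannot tell apart from injection. Esm1 changed by -3.90 ± 0.48 (adjusted p = 9.9e-05) to 4.28, as low as Eif2s3y on female arrays, Apln by -2.70 ± 0.35, Adm by -2.38 ± 0.39, Angpt2 by -1.77 ± 0.31 and Vegfa by -0.81 ± 0.18. The endothelial genes Cdh5, Emcn and Pecam1 fell by 1.27, 1.24 and 0.85, and the pericyte genes Cspg4 and Rgs5 by 1.39 and 0.81, with Pdgfb at -0.92 ± 0.17. Pdgfrb (-0.49 ± 0.17), Plvap (-0.37 ± 0.17), Gfap (-1.0 ± 0.72), Lcn2 (-0.62 ± 1.13) and Cx3cr1 (-0.33 ± 0.23) did not pass. On the same arrays all 14 lens genes rose (14 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation), among them the crystallins Crygs by 7.68 ± 1.33, Cryba4 by 7.15 ± 1.31, Crygb by 7.10 ± 1.15 and Cryaa by 6.66 ± 1.31. Crygs averaged 5.25 in untreated OIR, within the 4.48 to 5.70 that Xist read on male arrays, so its rise is a lower bound. Genes of the retinal pigment epithelium rose in 8 of 13 cases (11 adjusted over the list alone; adjusted p = 0.15 with an estimated correlation), including the visual cycle genes Rgr (2.85 ± 0.61), Rpe65 (2.83 ± 0.75) and Lrat (2.41 ± 0.54).

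In that comparison 1077 genes changed, 472 higher and 605 lower, and camera called 17 lists. The tip cell list fell, with 11 of 16 members lower (13 adjusted over the list alone), and so did the vessel stabilisation list, 9 of 20 (12 adjusted over the list alone); both calls held at adjusted p = 0.032 with an estimated correlation. In the HIF target list 18 of 29 members fell and Car12, a carbonic anhydrase gene, rose (20 and 1 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation). Members also fell in the endothelial list (10 of 22; 13 adjusted over the list alone; adjusted p = 0.091 with an estimated correlation), the pericyte list (10 of 20; 14 adjusted over the list alone; adjusted p = 0.091 with an estimated correlation) and the cell cycle list (8 of 23; 12 adjusted over the list alone, with 1 higher; adjusted p = 0.16 with an estimated correlation). Basement membrane genes fell in 8 of 28 cases (9 adjusted over the list alone, with 1 higher; adjusted p = 0.33 with an estimated correlation). The count was 136 with the lens list mean as a covariate, under which Cryaa turned to -0.35, 118 when only these 6 arrays were fitted, 1950 with array weights and 2753 with the hybridisation control mean. It was 489 without P5 saline replicate 1, 529 without OIR replicate 3 and 637 without OIR replicate 2.

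Between the 2 saline groups, which separate in injection day, hybridisation controls, lens genes and, if the series design text holds, collection day, 3438 genes differed, 2376 higher and 1062 lower at P5. Crystallins were higher at P5, Crygb by 8.31 ± 1.15 and Crygs by 7.85 ± 1.33 (lower bounds, as both lay at 5.08 or below after saline at P12), and all 14 lens genes rose (14 adjusted over the list alone; adjusted p = 0.42 with an estimated correlation). Esm1 (-2.94 ± 0.48), Adm (-2.34 ± 0.39), Apln (-2.22 ± 0.35) and Igfbp3 (-1.90 ± 0.40) fell, and Ero1a, a hypoxia-induced folding oxidase, changed by -1.69 ± 0.18. Pecam1 fell by 1.38, Angpt2 by 1.43, Vegfa by 0.63, Rgs5 by 0.89 and the microglial receptor gene Cx3cr1 by 0.70. Camera called 15 lists, none of them with an estimated correlation. HIF targets fell in 16 of 29 cases (18 adjusted over the list alone; adjusted p = 0.42 with an estimated correlation), cell cycle genes in 14 of 23 (15 adjusted over the list alone; 0.3), and endothelial genes in 9 of 22 (10 adjusted over the list alone; 0.42). The share of changed genes that were higher, 69.1%, was 50.2% after quantile normalization and 35.1% after median centring, which moved the median of all genes to -0.15; the count was 5959 with array weights and 2126 with the lens list mean as a covariate, under which Cryba4 turned to -0.12.

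Cells injected at P12 were compared with saline at P12, arrays that share the higher hybridisation controls, to ask what each cell type added once OIR was under way. After ECFC, Slc2a2, coding the glucose transporter GLUT2, rose by 1.13 ± 0.19 and Nectin4, an epithelial adhesion gene, by 1.12 ± 0.19 (both adjusted p = 0.032). Slc2a2 averaged 5.09 after saline, as low as Xist on male arrays, and 4.48 in untreated OIR. Its rise is therefore not an estimate of size and need not be a lower bound. Nectin4 was lowest of all groups after saline at P12 (6.49), against 7.61 with ECFC, 7.18 in untreated OIR and 6.95 in normoxia. Slc2a2 and Nectin4 were the only genes of 12393 to pass, with 1996 at an unadjusted p under 0.05 where chance gives 619.65. Several vessel genes had negative values that did not pass: Esm1 -0.97 ± 0.48, Angpt2 -0.80 ± 0.31, Tie1, an endothelial receptor, -0.83 ± 0.21 (adjusted p = 0.12), Vegfa -0.45 ± 0.18 (0.25) and Pecam1 -0.32 ± 0.17. Plvap (0.05 ± 0.17) and Pdgfb (0.17 ± 0.17) were positive and did not pass either. The pericyte genes Rgs5 (-0.13 ± 0.16), Cspg4 (-0.19 ± 0.18) and Pdgfrb (-0.16 ± 0.17) lay within about their errors of 0. Both calls ended without any 1 of 5 arrays (P12 saline replicate 1, 2 or 3, or ECFC replicate 2 or 3, each 0 genes), whereas 319 genes passed without ECFC replicate 1. The count was also 0 with the lens covariate, with dim genes left out, with only these 6 arrays in the fit, and without the 2 P12 arrays of lowest interquartile range, but 4 with the replicate block, 6 with trend and robust settings, 11 after quantile normalization and 3296 with array weights.

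As groups, 8 lists moved after ECFC at P12, none of them with an estimated correlation. Lower were HIF targets (27 of 29 members negative, 0 passing, 0 adjusted over the list alone), the endothelial list (19 of 22 negative; 1 adjusted over the list alone) and the tip cell list (12 of 16; 0). Lower as well were the cell cycle list (20 of 23; 8 adjusted over the list alone, with Rrm2 at -1.05 ± 0.30 and Top2a at -0.94 ± 0.29), the gliosis list (19 of 24; 0) and the unfolded protein response list (15 of 20; 0). Higher were the T and NK cell list (15 of 16 positive; 0) and the neutrophil list (13 of 14; 5 adjusted over the list alone, with S100a9, an abundant neutrophil protein, at 1.22 ± 0.35). Each of them had adjusted p = 0.78 with an estimated correlation, except gliosis, which had adjusted p = 0.79 with an estimated correlation. The HIF and tip cell calls ended without ECFC replicate 1 (adjusted p = 0.138 and 0.181), the gliosis and unfolded protein calls without P12 saline replicate 3 (0.139 and 0.0825), and the T and NK cell and unfolded protein calls after quantile normalization (0.137 and 0.0793). With dim genes left out the HIF and cell cycle calls remained (adjusted p = 0.0101 each), the endothelial (0.1), tip cell (0.07), gliosis (0.105) and unfolded protein (0.1) calls ended, and the T and NK cell and neutrophil lists had under 5 members left to test. The T and NK cell list averaged 6.17, 6.62 and 6.49 in ECFC replicates 1, 2 and 3, whose interquartile ranges were 3.40, 3.04 and 3.20, against 6.14, 6.08 and 6.13 after saline (interquartile range 3.44 ± 0.0275, SD, n = 3). The neutrophil list averaged 6.47, 6.30 and 6.14 in the same 3 arrays, against 5.84, 5.87 and 5.92.

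CD34+ cells at P12 left no gene past limma's threshold (0 genes; 643 at an unadjusted p under 0.05; 1 without CD34 replicate 1, 533 with array weights). The genes with the smallest p, none passing, were Myh3, an embryonic myosin (1.92 ± 0.41, adjusted p = 0.85), the muscle regulator Myf6 (0.74 ± 0.17) and Emc4 (0.46 ± 0.11). Vegfa was -0.23 ± 0.18, Angpt2 -0.26 ± 0.31, Esm1 -0.66 ± 0.48, Pecam1 -0.11 ± 0.17 and Gfap -0.97 ± 0.72. Camera called 6 lists lower: HIF targets (25 of 29 negative), gliosis (23 of 24), cell cycle (19 of 23), endothelial (14 of 22), rod (17 of 24) and immediate early genes (14 of 21), with 0 members adjusted over the list alone in each and adjusted p = 1 with an estimated correlation. Of these 6 calls 1 was left without P12 saline replicate 3, and each ended in at least 1 fit with an array left out (highest adjusted p from 0.0767 for gliosis to 0.744 for immediate early genes); quantile normalization ended the endothelial (0.128), rod (0.434) and immediate early (0.0543) calls. With dim genes left out the HIF and gliosis calls remained, and the endothelial (0.305), rod (0.224), cell cycle (0.0605) and immediate early (0.284) calls ended.

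With the combination at P12, 0 genes passed in limma (1226 at an unadjusted p under 0.05; 2 without combination replicate 1, 50 with array weights). Smallest in p were Tat, tyrosine aminotransferase (0.61 ± 0.11, adjusted p = 0.13), Alpk2 (1.03 ± 0.22) and Adgrb1, an inhibitor of vessel growth (0.55 ± 0.12). Vegfa was -0.33 ± 0.18, Esm1 -0.36 ± 0.48, Angpt2 -0.45 ± 0.31, Rgs5 0.07 ± 0.16 and Pdgfb 0.31 ± 0.17. HIF targets (27 of 29 negative), gliosis (22 of 24) and cell cycle genes (19 of 23) were called lower as lists, and T and NK cell (15 of 16 positive) and neutrophil genes (12 of 14) higher. Adjusted over the list alone 1 neutrophil gene passed and 0 in the other lists, and all 5 calls had adjusted p = 0.97 with an estimated correlation. The gliosis call ended without combination replicate 2 (adjusted p = 0.106) and the neutrophil call without replicate 3 (0.249) and after quantile normalization (0.254). With dim genes left out the first 3 remained and the T and NK cell and neutrophil lists had under 5 members left to test. The T and NK cell list averaged 6.30, 6.39 and 6.53 and the neutrophil list 5.97, 5.92 and 6.26 in combination replicates 1, 2 and 3, whose interquartile ranges were 3.32, 3.30 and 3.06. Neither the combination against ECFC (0 genes; 263 at an unadjusted p under 0.05), against CD34+ cells (0; 561), nor the test for more or less than the sum of both (0; 776) gave a gene at P12. The mean of all cell groups against saline gave 0 genes as well (1770 at an unadjusted p under 0.05; 52 without ECFC replicate 1, 18 without combination replicate 1, 1 without CD34 replicate 2, 8 with the hybridisation control covariate and 2158 with array weights). With array weights the other 3 counts were 4, 8 and 523.

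**Figure D3:**
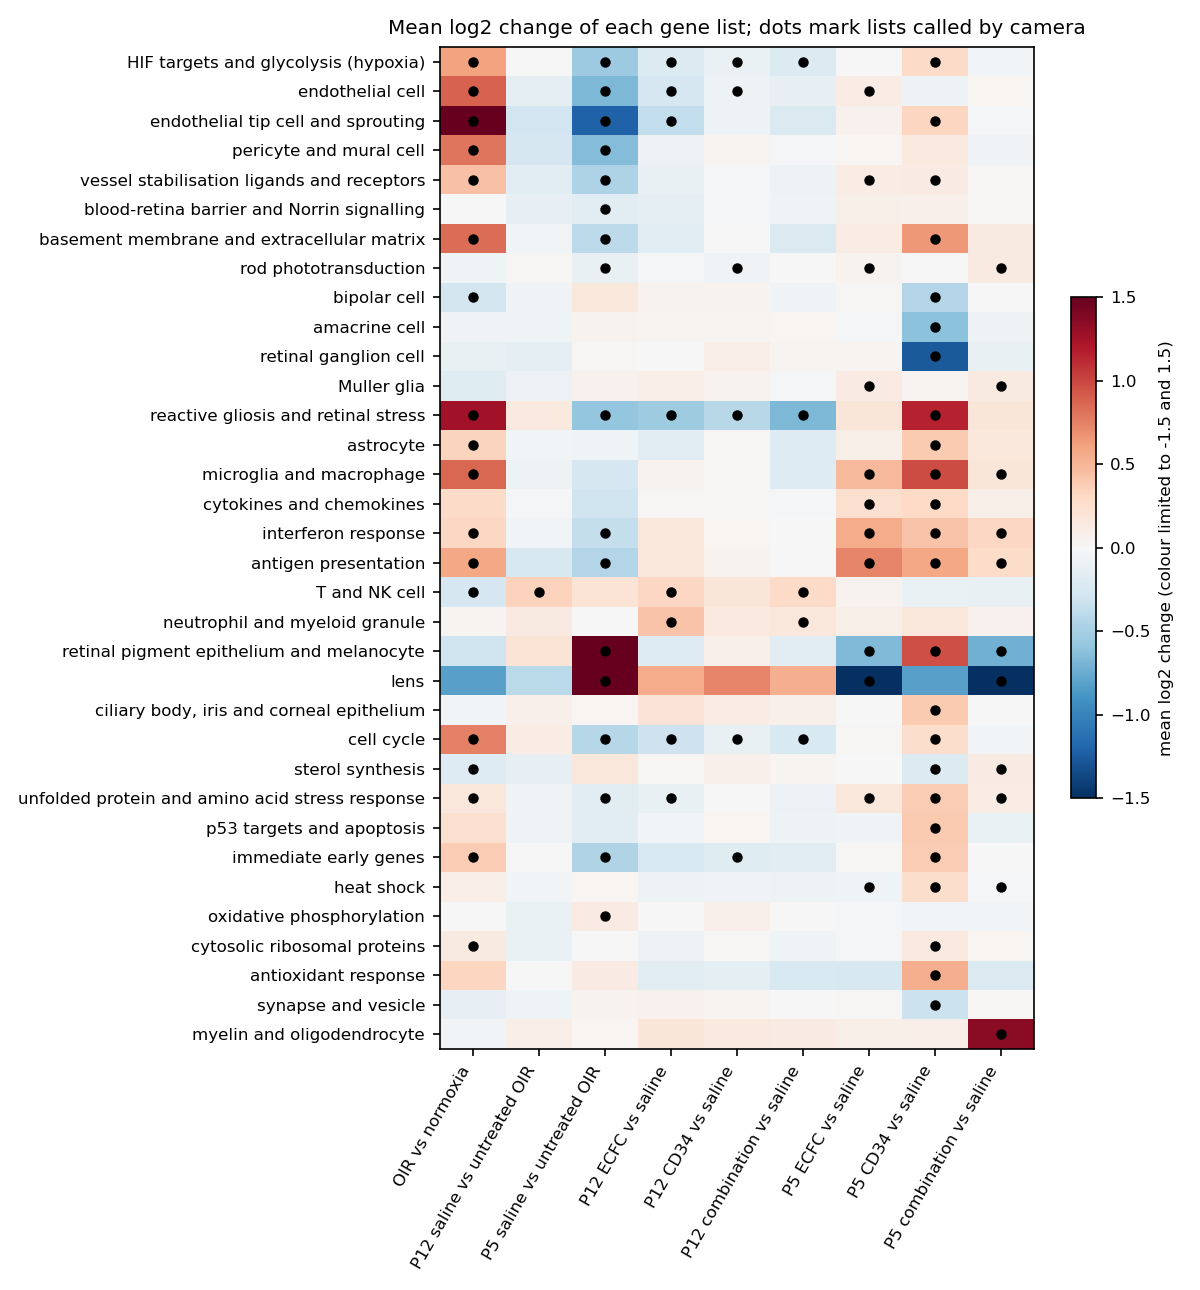
Mean log2 change of the members of each gene list (rows of the plot) in 9 comparisons (columns), shown for lists that camera called at least once. Red is higher and blue lower in the first-named group, colour is limited to -1.5 and 1.5, and black dots mark calls with the preset correlation. The tip cell list was 1.72 higher in OIR than in normoxia, and the ganglion cell list was at -1.26 after CD34+ cells at P5.

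CD34+ cells at P5 changed 1049 genes, 380 higher and 669 lower than after saline at P5. Genes of ganglion, amacrine and bipolar cells fell, while the horizontal cell list was not called (mean 0.01; adjusted p = 0.546). Slc17a6, the vesicular glutamate transporter of ganglion cells, changed by -2.85 ± 0.59 (adjusted p = 0.005), from 10.2 ± 0.436 to 7.32 ± 2.20 (SD, n = 3). Its SE and p use 1 spread shared by all 10 groups, and the CD34 arrays varied more than the saline arrays. Rbpms, a ganglion cell marker, changed by -1.17 ± 0.24. The axon growth gene Gap43 fell by 1.14, Stmn2 by 1.38 and Nell2 by 1.40, and of the ganglion cell list 15 of 16 members fell (16 adjusted over the list alone; adjusted p = 0.1 with an estimated correlation). In the amacrine list 8 of 16 fell (13 adjusted over the list alone; adjusted p = 0.16 with an estimated correlation), such as Gad2, a GABA synthesis enzyme (-0.90 ± 0.19), and Tfap2b (-0.69 ± 0.12). In the bipolar list 8 of 13 fell, such as Pcp2 (-0.79 ± 0.15) and Prkca (-0.54 ± 0.10), and 1 rose (10 and 1 adjusted over the list alone; adjusted p = 0.16 with an estimated correlation). That 1 was Trpm1, the channel of ON bipolar cells, at 1.31; melanocytes also express it. Synapse genes fell in 6 of 17 cases (8 adjusted over the list alone; adjusted p = 0.053 with an estimated correlation), while the rod list, at a mean of 0.01, and the cone list were not called.

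The genes that rose most after CD34+ cells at P5 are given among those that passed and whose arrays separated fully from saline. They were Gpnmb, a glycoprotein of phagocytes and pigment cells (2.91 ± 0.53, adjusted p = 0.0028), Serping1 (2.24 ± 0.63), Fbln1 (2.24 ± 0.61), the macrophage lectin Lgals3 (2.23 ± 0.70) and Cox8b (2.22 ± 0.37). Pigment genes rose in 5 of 13 cases (6 adjusted over the list alone; adjusted p = 0.18 with an estimated correlation), including Tyrp1 at 2.11 ± 0.55 and Dct at 1.76 ± 0.43. Basement membrane and matrix genes rose in 10 of 28 (15 adjusted over the list alone, with 1 lower; adjusted p = 0.1 with an estimated correlation), among them Col1a1 (1.94 ± 0.58), Col1a2 (1.63 ± 0.39) and Bgn (1.15 ± 0.27). Microglia and macrophage genes passed in 3 of 22 cases (16 adjusted over the list alone; adjusted p = 0.23 with an estimated correlation): C1qb 1.26 ± 0.38, Aif1 1.23 ± 0.34 and Csf1r 0.99 ± 0.30. The unfolded protein response rose in 7 of 20 (13 adjusted over the list alone; adjusted p = 0.054 with an estimated correlation), with Xbp1 at 0.71 ± 0.13 and the chaperone gene Hspa5 at 0.50 ± 0.09. With the preset correlation camera had called this list lower after saline at P5 than in untreated OIR. Xbp1 averaged 9.29 after saline at P5, 10.01 with CD34+ cells at P5 and 10.06 in untreated OIR. In the p53 list 3 of 15 rose (5 adjusted over the list alone, with 1 lower; adjusted p = 0.054 with an estimated correlation), with the death receptor gene Fas at 1.16 ± 0.19. Antioxidant genes rose in 4 of 15 (7 adjusted over the list alone, with 1 lower; adjusted p = 0.1 with an estimated correlation), such as Mgst1 at 1.81 ± 0.33. Of the vessel genes Plvap rose by 0.60 ± 0.17 (adjusted p = 0.028), whereas Vegfa (-0.13 ± 0.18), Esm1 (1.10 ± 0.48), Pecam1 (-0.24 ± 0.17), Rgs5 (0.13 ± 0.16), Cspg4 (0.37 ± 0.18) and Gfap (1.47 ± 0.72) did not pass.

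The CD34 arrays at P5 were unlike one another, while the test assumes 1 spread per gene shared by all 10 groups. The mean of the ganglion cell list was 8.13, 9.89 and 8.63 in CD34 replicates 1, 2 and 3, against 9.80, 10.33 and 10.30 after saline, and the mean of the microglia list was 10.09, 7.78 and 8.58 against 8.27, 7.64 and 7.61. The lens list mean was 7.63 in CD34 replicate 1 and 14.1 and 13.997 in the others. Camera called 24 lists in this comparison, 19 higher and 5 lower, none with an estimated correlation. The count of genes was 461 without P5 saline replicate 3 and 682 without CD34 replicate 1, 1771 with the hybridisation control covariate, 2525 with array weights, and 0 when only these 6 arrays were fitted.

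**Figure D4:**
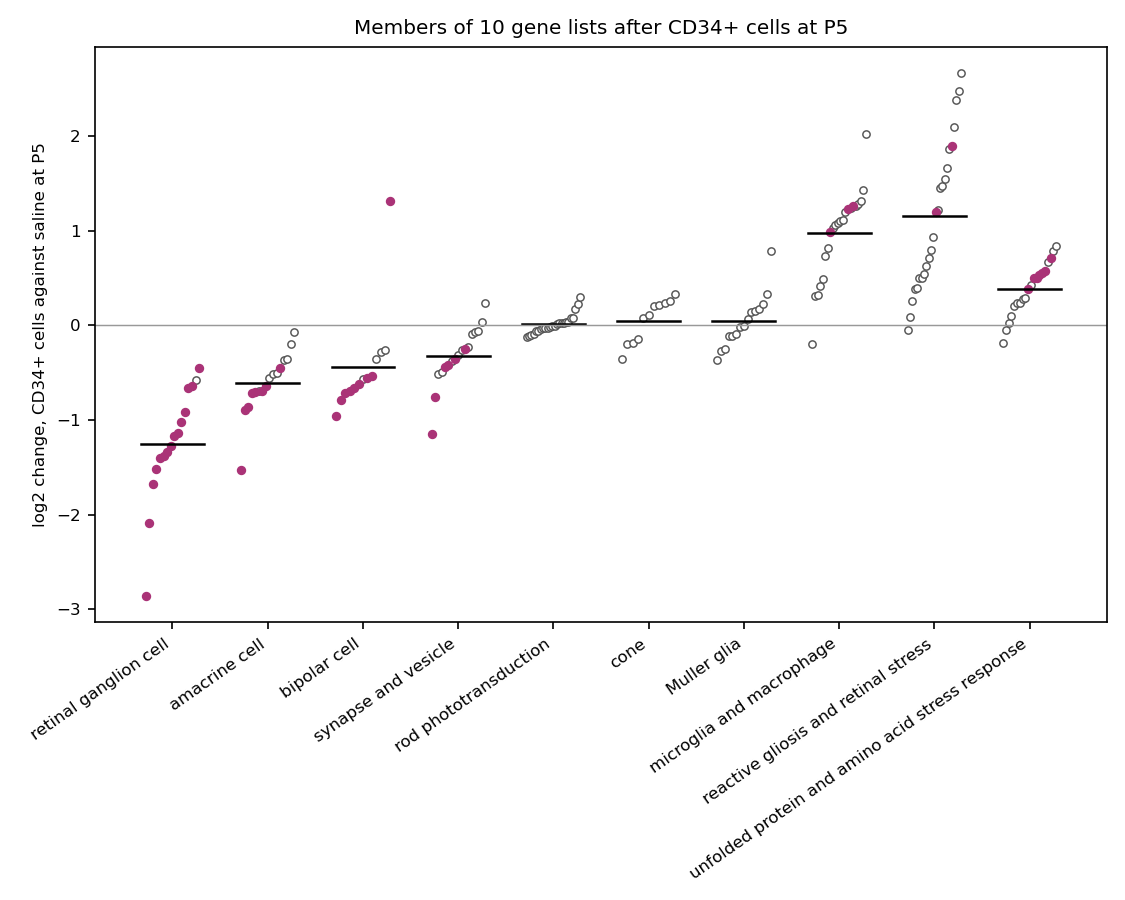
Log2 change after CD34+ cells against saline at P5 for the measured members of 10 gene lists. Each point is 1 gene (n = 3 arrays per group), filled points passed limma's adjusted p threshold of 0.05, and the line is the mean of the list. The ganglion cell list averaged -1.26, the rod list 0.01 and the microglia list 0.98.

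ECFC at P5 left 0 genes past limma's threshold (779 at an unadjusted p under 0.05; 6 without ECFC replicate 1, 5 without P5 saline replicate 3). The count was 57 with array weights and 641 with the hybridisation control covariate. The smallest p belonged to Xbp1, a transcription factor of the unfolded protein response (0.72 ± 0.13, adjusted p = 0.089), Birc3, an inhibitor of apoptosis (0.65 ± 0.12, 0.089), and Slc44a4 (-0.63 ± 0.13, 0.16). Slc44a4 (5.05 with ECFC, 5.68 after saline) and Birc3 after saline (5.56) read as low as Xist on male arrays. Their changes are not estimates of size. Immune lists were called higher: antigen presentation (14 of 15 positive; 8 adjusted over the list alone), with H2-Ab1 at 1.24 ± 0.41 and B2m at 1.07 ± 0.34, the interferon response (19 of 19; 0 adjusted over the list alone), with Ifit1 at 1.22 ± 0.46, and microglia (19 of 22; 0 adjusted over the list alone), with Lyz2 at 1.53 ± 0.78. The adjusted p was 0.14, 0.14 and 0.67 with an estimated correlation, and without ECFC replicate 3 camera's adjusted p rose to 0.0632, 0.0681 and 0.135; the lens covariate ended the microglia call (0.82). The unfolded protein list was higher too (6 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation), against saline arrays in which camera had called it lower than in untreated OIR. Lens genes (14 of 14 negative; 11 adjusted over the list alone; adjusted p = 0.2 with an estimated correlation) and pigment epithelium genes (12 of 13 negative; 0 adjusted over the list alone; adjusted p = 0.62 with an estimated correlation) were lower, with Rpe65 at -1.71 ± 0.75; the pigment call ended without P5 saline replicate 2 (0.629). In all 12 lists were called, none with an estimated correlation, and 3 without ECFC replicate 3; for the heat shock list the test and the median (0.08) were positive and the mean negative (-0.07). Vegfa was -0.33 ± 0.18, Pecam1 0.00 ± 0.17, Rgs5 0.28 ± 0.16, Pdgfrb 0.03 ± 0.17 and Cspg4 0.37 ± 0.18.

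The combination at P5 left 0 genes past the threshold in limma (978 at an unadjusted p under 0.05). That count was 17 without P5 saline replicate 3, 235 with array weights and 575 with the hybridisation control covariate. Xbp1 was among the smallest p (0.77 ± 0.13, adjusted p = 0.067), with Emid1 (-0.88 ± 0.18) and C920021L13Rik (-0.56 ± 0.11). All P5 cell groups were compared with the same 3 saline arrays, in which Xbp1 averaged 9.29. Xbp1 averaged 10.02, 10.01 and 10.07 with ECFC, CD34+ cells and the combination at P5. It averaged 10.06 in untreated OIR, 9.77 in normoxia and 9.65 after saline at P12. Rod genes were slightly higher as a list, by 0.13 on average with 23 of 24 positive (0 adjusted over the list alone; adjusted p = 0.5 with an estimated correlation), such as Rp1, a gene of the outer segment axoneme (0.29 ± 0.12). Myelin genes were called higher, 11 of 11 positive (8 adjusted over the list alone; adjusted p = 0.43 with an estimated correlation), with Cldn11 at 2.58 ± 0.76, Olig1 at 1.92 ± 0.68 and Mobp at 1.73 ± 0.65. That list averaged 9.70 in combination replicate 2 and 5.93 and 6.24 in the others, and the call ended without that array (adjusted p = 0.0833). With dim genes left out the myelin list had under 5 members to test. The interferon list (16 of 19 positive; 0 adjusted over the list alone; adjusted p = 0.52 with an estimated correlation) and the unfolded protein list (14 of 20; 5 adjusted over the list alone; adjusted p = 0.47 with an estimated correlation) were higher. Lens (14 of 14 negative; 0 adjusted over the list alone; adjusted p = 0.58 with an estimated correlation) and pigment genes (13 of 13 negative; 0 adjusted over the list alone; adjusted p = 0.5 with an estimated correlation) were lower, the pigment call ending without P5 saline replicate 2 (0.157). Camera called 11 lists, none with an estimated correlation. For heat shock the median was 0.08 and the mean -0.03, and the call ended with dim genes left out (adjusted p = 0.0592). Vegfa was -0.28 ± 0.18, Angpt2 0.02 ± 0.31, Esm1 -0.15 ± 0.48, Pecam1 0.01 ± 0.17, Pdgfrb -0.12 ± 0.17 and Rgs5 0.18 ± 0.16.

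Setting the P5 cell treatments side by side tested the addition of ECFC to CD34+ cells. The combination differed from CD34+ cells alone at 970 genes, 529 higher and 441 lower, with 1 spread per gene shared by all 10 groups. Slc17a6 was 2.71 ± 0.59 higher (adjusted p = 0.0067), Tmem163 1.87 ± 0.44 and Sncg, a ganglion cell synuclein, 1.82 ± 0.50, followed by Tspan2 (1.73 ± 0.47) and Apod (1.71 ± 0.47). Both calls ended without combination replicate 2, in which the myelin list averaged 9.70 (Tspan2 0.72, adjusted p = 0.114; Apod 1.05, 0.224). Gpnmb was lower by -3.69 ± 0.53 (adjusted p = 0.00036), the stress gene Nupr1 by -3.23 ± 0.66, Tent5c by -3.22 ± 0.62, B3gnt5 by -3.21 ± 0.62 and Metrnl by -3.08 ± 0.47. That count was 379 without combination replicate 2, 464 without combination replicate 1, 641 without CD34 replicate 1, 2627 with array weights and 0 when only these 6 arrays were fitted. The combination against ECFC gave 0 genes (151 at an unadjusted p under 0.05; 82 with array weights).

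Over all cell-treated P5 retinas (n = 9 against 3), 13 genes changed, 6 higher and 7 lower. Higher were Xbp1 (0.74 ± 0.11, adjusted p = 0.0067), the glycolytic enzyme gene Hk2 (0.60 ± 0.11), the folding enzyme gene Pdia6 (0.50 ± 0.10), Birc3 (0.48 ± 0.09) and Hspa5 (0.43 ± 0.07). Birc3 averaged 5.56 after saline, as low as Xist on male arrays, so its rise is not an estimate of size. Trhr, a hormone receptor gene (-0.72 ± 0.13), Acr (-0.69 ± 0.13), Rasgrp2 (-0.65 ± 0.12), Proser1 (-0.55 ± 0.10) and C920021L13Rik (-0.47 ± 0.09) were lower. The lens list averaged 12.7 after saline and 9.46, 11.9 and 10.3 in the cell-treated P5 groups, and with the lens covariate the count was 0, as without P5 saline replicate 1 or with only the P5 arrays in the fit. It was 49, 20, 32, 8 and 5 without CD34 replicate 2, CD34 replicate 3, P5 saline replicate 2, P5 saline replicate 3 and combination replicate 2. It was 26 with dim genes left out, 42 after quantile normalization, 404 with array weights and 1322 with the hybridisation control covariate.

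The combination at P5 departed from the sum of its parts at 23 genes, 16 above the sum and 7 below. Vipr2, a neuropeptide receptor gene (1.15 ± 0.19, adjusted p = 0.013), Rasgrp2 (1.14 ± 0.20), Rgs7, a G protein regulator of ON bipolar cells (1.09 ± 0.22), Ankrd6 (0.98 ± 0.19) and Oprm1 (0.91 ± 0.19) were above it. Gpnmb (-3.92 ± 0.75), Aldh1a1, a retinoic acid synthesis enzyme (-1.33 ± 0.27), Birc3 (-1.12 ± 0.16, adjusted p = 0.0067), Pdia6 (-1.0 ± 0.17) and Hk2 (-0.94 ± 0.19) were below it. Since Birc3 averaged 5.56 after saline, as low as Xist on male arrays, its value is not an estimate of size. Leaving out 1 array moved the count of 23 from 2 (combination replicate 1) to 435 (CD34 replicate 2), and fitting only the P5 arrays gave 0. The count was 141 after quantile normalization, 351 with the hybridisation control covariate and 1508 with array weights.

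The timing of injection was tested as the difference between the cell effect at P5 and that at P12. The P5 and P12 groups also separate in hybridisation controls, lens genes and, if the series design text holds, collection day. The test cannot tell injection day apart from these. For CD34+ cells 235 genes differed, 50 with a more positive effect at P5 and 185 with a more negative one. Gpnmb had effects of 2.91 at P5 and -0.11 at P12 (difference 3.02 ± 0.75, adjusted p = 0.041), Emp1 of 1.99 and -0.32 (2.31 ± 0.48), and Stmn2 of -1.38 and 0.15 (-1.53 ± 0.39). For ECFC 4 genes differed: Nectin4 (-1.77 ± 0.27, adjusted p = 0.013), Slc2a2 (-1.48 ± 0.26), H2bc18 (-0.91 ± 0.17) and Xbp1 (1.03 ± 0.19). Nectin4 averaged 7.45 after saline at P5 and 6.49 after saline at P12, against 6.81 and 7.61 with ECFC, so the saline groups differed too. Slc2a2 (4.66 and 5.01) and H2bc18 (4.91 and 5.18) read as low with ECFC and saline at P5 as Xist on male arrays, so no effect at P5 can be measured for them and their differences are not estimates of size. For the combination 0 genes differed in limma (1419 at an unadjusted p under 0.05; 4 without P12 combination replicate 1). The CD34 count was 13 without P12 saline replicate 3, 766 without P5 CD34 replicate 2 and 0 with only its own groups in the fit. With 1 array left out the ECFC count ranged from 0 to 32, the highest without P12 ECFC replicate 1; it was 12 after quantile normalization, 1489 with the hybridisation control covariate and 1518 with array weights. With that covariate and with array weights the CD34 count was 1062 and 2139 and the combination count 1049 and 227.

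An OIR signature asked whether cell treatment moved OIR genes toward normoxia: the 100 genes highest and 100 lowest by limma's moderated t for untreated OIR against normoxia. The score is the mean of the former minus that of the latter, divided by 2. Because the genes were chosen on the normoxia and untreated OIR arrays, the choice widens the span between those groups. That span, of which shares are given below, is therefore no separate result. The score was -0.77 ± 0.09 (SD, n = 3) in normoxia, 0.26 ± 0.15 in untreated OIR, 0.17 ± 0.08 after saline at P12 and -0.37 ± 0.06 after saline at P5. ECFC at P12 moved it by -0.30 against saline (-29.4% of the span from normoxia to OIR; limma's fry, adjusted p = 0.00424 over 6 comparisons; 3 of 3 arrays below the saline mean). CD34+ cells (-0.14, adjusted p = 0.113) and the combination (-0.17, 0.113) at P12 did not pass, with 3 of 3 arrays below the saline mean in each; without P12 saline replicate 1 both passed at -0.17 and -0.21 (0.0445), and CD34+ cells also without CD34 replicate 3 (-0.19, 0.031). At P5, CD34+ cells moved the score away from normoxia by 0.26 (25.1%, adjusted p = 0.0157; 3 of 3 arrays above the saline mean). Of the 100 genes higher in OIR, those in the tip cell list (9) averaged 0.45 in this comparison, those in the matrix list (8) 0.46, in the cell cycle list (6) 0.63 and in the endothelial list (8) 0.03. The lists overlap (Nid2 is in the tip cell and the matrix list), so these means cannot tell vessel genes from others. The signature call for CD34+ cells at P5 ended without P5 saline replicate 1 (0.24, adjusted p = 0.066) or replicate 3 (0.25, 0.0512). ECFC and the combination at P5 gave 0.04 each (adjusted p = 0.704). Whether these shifts differed from one another was not tested.

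**Figure D5:**
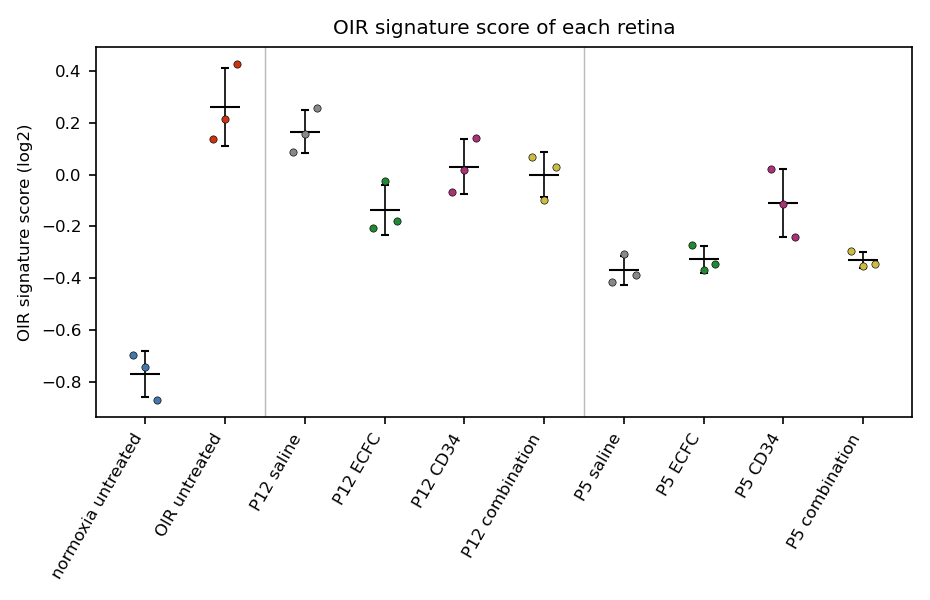
OIR signature score (log2) of each retina in 10 groups. Points are arrays, marks are means of 3 and bars are ± 1 SD. Normoxia averaged -0.77, untreated OIR 0.26, ECFC at P12 -0.14 and saline at P12 0.17.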

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

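Tests of the P12 pattern, both dilution tests and the lens covariate were chosen only after the results were seen; the tests of collection day, of single arrays and of other splits were written before. The effect of CD34+ cells differed between injection at P5 and at P12 by a test of the difference itself at 235 genes. The differences were 3.02 for Gpnmb, 2.36 for Synpo, 2.31 for Emp1, 2.11 for Cox8b, 1.95 for Mgst1, -1.53 for Stmn2, -1.77 for Kcnd2, -1.78 for Scn11a, -1.84 for Fkbp1b and -2.39 for Myh3. For Myh3 the effects were -0.47 at P5 and 1.92 at P12, where the CD34 arrays were uneven (7.70 ± 1.35, against 5.78 ± 0.05 after saline, SD, n = 3). The effect of ECFC differed by the same kind of test at 4 genes. The differences were 1.03 for Xbp1, -0.91 for H2bc18, -1.48 for Slc2a2 and -1.77 for Nectin4. Part of the Nectin4 difference lay between the saline groups (7.45 at P5, 6.49 at P12). At P5 Slc2a2 and H2bc18 read as low as Xist on male arrays (4.48 to 5.70), so their differences are not estimates of size, and Scn11a did so after CD34+ cells at P5 (5.54). In data outside the gene comparisons, the spiked-in hybridisation controls were 0.88 higher on the 12 arrays of the P12 groups than on the 18 others. Neither timing test can tell injection day apart from hybridisation controls, lens genes or, if the series design text holds, collection day.

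Of the 100 splits drawn for the CD34 timing test 1 gave as many genes, the real one (235, highest other 132). These splits shuffled CD34 and saline labels within each injection day. They test for no CD34 effect on either day, so they cannot exclude chance for a difference between the days. For ECFC timing 5 of 100 splits gave as many as the real 4 (highest other 943), so chance is not excluded. What gave a split that many calls was not tested.

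The first pattern is that saline at P12 differed from untreated OIR at 2642 genes. The hybridisation controls, which hold no retinal RNA, were 0.884 higher on the P12 arrays, 3.57 times the SD within groups (0.248). The permutation p was 1e-05, the smallest the permutations can give, with single arrays and not groups permuted. Separate hybridisation of those arrays would give such a difference. A change made by the injection itself stays open: 96.3% of the called genes differed the same way between the cell-treated P12 and P5 arrays, and 96.9% between cell-treated P12 and normoxia arrays, which both explanations predict. All retinas injected at P12 lie on those arrays, so batch and injection cannot be told apart for these genes. Comparisons within the P12 groups do not cross it.

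The second pattern is the lower hypoxia, vessel and pericyte lists after saline at P5. Dilution by lens RNA as the source of the lower vessel lists is argued against: vessel lists moved by -0.66 and neuron lists by 0.01. That is a difference of -0.67 (95% interval -0.87 to -0.47). Within the neuron lists the rods moved the way dilution would. Camera called the rod list lower than in untreated OIR, a call that ended with dim genes left out (adjusted p = 0.0512). Against normoxia the rod list was at -0.17 (camera adjusted p = 0.00015, with the lens covariate 0.94). Collection at P12, as the series design text reads, could be a source by the test written beforehand: a list of immature neuron genes was 0.17 higher than in normoxia (95% interval 0.0577 to 0.277; limma's camera, adjusted p = 0.0493 over 38 lists) and HIF targets were not (adjusted p = 0.789). With the lens covariate, a condition added after that value was seen, the immature list did not pass (adjusted p = 0.35) and HIF targets were higher by the unadjusted threshold of that test (adjusted p = 0.0999), which it counts against this source; tip cell genes (0.50; adjusted p = 0.0013, with the covariate 0.0402) and cell cycle genes (0.32; 0.00162 and 0.00344) were above normoxia too. The values point both ways, so collection day stays open, as does an effect of the early injection, which was not tested apart from it.

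The third pattern is the change of 1049 genes after CD34+ cells at P5. Dilution by RNA of lens, pigment epithelium or blood cells is argued against for the lower neuron lists. Ganglion, amacrine and bipolar cell lists moved by -0.79 and rods by 0.01. That is a difference of -0.80 (95% interval -1.27 to -0.34), or -0.67 (-1.08 to -0.26) with the horizontal cell list, itself at 0.01, added. RNA of other tissue as a source of the 380 higher genes was not tested. Tyrp1 averaged 8.52 after saline and 10.6 with CD34+ cells. Camera also called the ciliary body, iris and corneal epithelium list higher (adjusted p = 0.0195 with dim genes left out, no call with an estimated correlation). That 1 array decides the calls stays open, since 443 of the 1049 genes were still called without P5 saline replicate 3, between the bounds set beforehand for the share kept. No biological explanation of the change was tested. Whether the cells or the injection did this cannot be told with 3 eyes that differ as much as these.

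For comparisons of 3 with 3 arrays the 10 splits are too few for a share under 0.05. In 7 of them 1 split, the real one, gave the highest count: OIR against normoxia 565 (highest other 0), P12 saline against OIR 2642 (0), P5 saline against OIR 1077 (0), P5 against P12 saline 3438 (0), P12 ECFC 2 (0), P5 CD34 1049 (758) and P5 combination against CD34 970 (491). In the others the real count was 0, which each of the 10 splits reaches by construction, so the splits say nothing about chance: P12 CD34 (highest other 0), P12 combination (0), P5 ECFC (72), P5 combination (2), P12 combination against ECFC (12) and against CD34 (0), and P5 combination against ECFC (0). Among comparisons with 100 splits, as many genes came from 15 for all P5 cells (real count 13; highest other 1416) and 14 for P5 non-additivity (23; 592), so chance is not excluded for these. For all P12 cells (0; 1298), P12 non-additivity (0; 46) and combination timing (0; 0) the 100 splits say nothing about chance either, since each reaches the real 0. What produced splits with counts many times the real one was not tested.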

How the results depend on the processing

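The lens, hybridisation control and Xist covariates and leaving out the 2 P12 arrays of lowest interquartile range were chosen only after the data were seen; the other settings were planned. All 6 signature shifts kept their direction and side of the threshold under quantile normalization, dim genes left out, the replicate block and 50 or 300 genes from each end. Of 6770 values of named genes under settings other than leaving out an array, 6066 kept direction and side of the threshold, 366 lost the call, 267 gained it, 67 moved and 4 reversed. With 1 array left out, 3734 of 4290 kept both, 491 lost the call and 65 gained it. The number of arrays limits the precision, and signal over background limits dim genes. Absent transcripts read 3.84 to 4.83 (Eif2s3y on female arrays) and 4.48 to 5.70 (Xist on male arrays). Changes from such levels are not estimates of size. The cause of the moves below was not tested, except where fewer or more features tested account for them by construction.

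Counts of changed genes are given by setting. With all probe sets as tested features, which tests more features, they were 935 (OIR against normoxia), 4836 (P12 saline against OIR), 1907 (P5 saline against OIR), 6138 (P5 against P12 saline), 0 (P12 ECFC), 1 (P5 ECFC), 1814 (P5 CD34), 1 (P5 combination), 1659 (P5 combination against CD34), 38 (P5 any cells), 53 (P5 non-additivity) and 2 (ECFC timing). At 1.5-fold or more they were 946 (P12 saline), 459 (P5 saline), 1397 (P5 against P12 saline), 596 (P5 CD34), 601 (P5 combination against CD34) and 5 (P5 any cells). With dim genes left out they were 0 (P12 ECFC), 1 (P5 combination), 26 (P5 any cells), 123 (P5 non-additivity), 0 (ECFC timing) and 1 (combination timing), and list calls were 0 (P12 saline), 2 (P12 ECFC) and 3 (P12 CD34). With trend and robust settings they were 6 (P12 ECFC), 1 (P5 combination) and 85 (P5 non-additivity).

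With array weights, from 0.198 to 4.63, all 21 counts moved: 852, 5300, 1950 and 5959 for OIR and the saline contrasts; 3296, 533 and 50 for P12 ECFC, CD34 and combination; 57, 2525 and 235 for the same at P5; 4 and 8 for the P12 combination against ECFC and CD34; 82 and 2627 for the same at P5; 2158 and 404 for any cells; 523 and 1508 for non-additivity; and 1518, 2139 and 227 for ECFC, CD34 and combination timing. The cause of those counts was not tested.

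Quantile normalization gave 11 (P12 ECFC), 2 (P5 ECFC), 1 (P5 combination), 42 (P5 any cells), 141 (P5 non-additivity) and 12 (ECFC timing), and 0 list calls for P12 saline. Median centring gave 1 (P12 ECFC), 1 (P5 ECFC), 1 (P5 combination), 23 (P5 any cells) and 117 (P5 non-additivity). With only the groups compared in the fit, counts were 348 (OIR), 3972 (P12 saline), 118 (P5 saline), 1 (ECFC timing) and 0 for P12 ECFC, P5 CD34, P5 combination against CD34, P5 any cells, P5 non-additivity and CD34 timing. With an estimated correlation, list calls were 6 for OIR against normoxia, 2 for P5 saline against OIR and 0 in the other 8 comparisons.

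Replicate numbers showed no pairing (correlations from -0.45 to 0.55), and with the replicate block counts were 4 (P12 ECFC), 1 (P5 ECFC), 63 (P5 non-additivity), 1 (ECFC timing) and 1 (combination timing), with the others within 1.5 times.

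The hybridisation control covariate gave 1661 (P12 saline), 2753 (P5 saline), 641 (P5 ECFC), 1771 (P5 CD34), 575 (P5 combination), 8 (P12 any cells), 1322 (P5 any cells), 351 (P5 non-additivity), and 1489, 1062 and 1049 for ECFC, CD34 and combination timing; Pgk2 reversed to -0.15 and 4930433N12Rik to -0.16. The lens covariate gave 136 (P5 saline), 2126 (P5 against P12 saline), 0 (P12 ECFC), 1 (P5 combination), 0 (P5 any cells), 63 (P5 non-additivity), 0 (ECFC timing) and 2 (combination timing); Cryaa reversed to -0.35 and Cryba4 to -0.12, by construction, since lens genes make the covariate. With Xist they were 20 (P5 any cells), 4 (P5 non-additivity), 1 (ECFC timing), 427 (CD34 timing) and 2 (combination timing). Without the 2 P12 arrays they were 0 (P12 ECFC) and 0 (ECFC timing), with 8 list calls for the P12 combination.

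With each array left out in turn, counts ran from 242 to 615 (OIR against normoxia), 1687 to 2134 (P12 saline), 489 to 1045 (P5 saline), 2603 to 3280 (P5 against P12 saline), 0 to 319 (P12 ECFC; 319 without ECFC replicate 1), 0 to 1 (P12 CD34), 0 to 2 (P12 combination), 0 to 6 (P5 ECFC; 6 without ECFC replicate 1, 5 without P5 saline replicate 3), 461 to 1454 (P5 CD34) and 0 to 17 (P5 combination; 17 without P5 saline replicate 3). They ran from 0 to 1 (P12 combination against ECFC), 0 to 1 (against CD34), 0 to 0 (P5 combination against ECFC), 379 to 1339 (against CD34), 0 to 52 (P12 any cells), 0 to 49 (P5 any cells), 0 to 1 (P12 non-additivity), 2 to 435 (P5 non-additivity), 0 to 32 (ECFC timing), 13 to 766 (CD34 timing) and 0 to 4 (combination timing). List calls ran from 12 to 21 (OIR), 1 to 3 (P12 saline), 14 to 21 (P5 saline), 14 to 19 (P5 against P12 saline), 6 to 12 (P12 ECFC), 1 to 6 (P12 CD34), 4 to 8 (P12 combination), 3 to 13 (P5 ECFC), 20 to 25 (P5 CD34) and 8 to 15 (P5 combination). Signature shifts ran from -0.36 to -0.26 (P12 ECFC), -0.19 to -0.0863 (P12 CD34), -0.21 to -0.12 (P12 combination), 0.01 to 0.07 (P5 ECFC), 0.19 to 0.32 (P5 CD34) and 0.02 to 0.07 (P5 combination).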

Other observations

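Other gene groups differed between untreated OIR and normoxia or between saline at P5 and untreated OIR. In untreated OIR, antigen presentation genes passed in 2 of 15 cases (7 adjusted over the list alone; adjusted p = 0.39 with an estimated correlation), with H2-Ab1, a class II gene, at 2.17 ± 0.41 and B2m at 1.22 ± 0.34 (limma, n = 3 against 3). Immediate early genes passed in 2 of 21, Zfp36 at 0.94 ± 0.17 and Jun at 0.79 ± 0.18 (4 adjusted over the list alone, adjusted p = 0.39 with an estimated correlation). That call ended without normoxia replicate 1 (adjusted p = 0.103) and with dim genes left out (0.0823). Ribosomal protein genes were 0.13 higher on average, with Rplp0 passing at 0.47 ± 0.12 (3 adjusted over the list alone; adjusted p = 0.38 with an estimated correlation). The sterol gene Nsdhl fell by 0.56, 1 of 15 in its list (3 adjusted over the list alone; adjusted p = 0.59 with an estimated correlation), and that call ended without OIR replicate 3 (0.16).

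After saline at P5, respiratory chain genes were 0.13 higher on average than in untreated OIR, with 2 of 25 members higher and 1 lower (6 and 2 adjusted over the list alone; adjusted p = 0.58 with an estimated correlation), such as Ndufb8 at 0.47 ± 0.08. In the unfolded protein list Hsp90b1 (-0.58 ± 0.10), Xbp1 (-0.77 ± 0.13) and Hspa5 (-0.40 ± 0.09) fell, 4 of 20 with 1 higher (8 and 1 adjusted over the list alone; adjusted p = 0.34 with an estimated correlation). In the immediate early list 3 of 21 fell, Zfp36 by 0.90, Klf6 by 0.66 and Fosl2 by 0.69 (3 adjusted over the list alone; adjusted p = 0.15 with an estimated correlation). With the lens covariate the unfolded protein and immediate early calls ended (adjusted p = 0.96 and 0.15).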
